A study of Arabidopsis thaliana with 4 samples.

How the data were processed

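The data were 4 single-colour Affymetrix oligonucleotide arrays hybridised with biotin-labelled total RNA of Arabidopsis seedlings, 2 of wild type and 2 titled as overexpressing At1g54160 (NFYA5). Groups and replicate numbers were taken from the sample titles. The design text of the series calls the second group an nfya5 mutant, and this conflict was left open. The deposited values are array intensities on a linear scale: per the submitters' processing notes they are MAS5 signals, and per the labels each array was scaled to a target signal of 500. The 2% trimmed mean of each array's signals was 500, as that scaling gives. The version of MAS5 was not given in the sources used here. Background correction belongs to the MAS5 signal, and no detection calls were used here, so that a filter on the mean signal took their place. Global scaling sets the total of every array equal, so a change shared by most transcripts could not be seen.

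Probe sets were named through the platform annotation supplied for the array, with symbols taken from the TAIR10.1 gene table. Of 22810 probe sets, 13513 named 1 gene, 503 named several genes, 8730 had no listed gene and 64 were control probe sets. Of those naming 1 gene, 13436 matched the gene table. A probe set without a listed gene is unnamed here, which does not mean that it has no gene, and no gene was named from a probe set with several. The annotation listed 0 probe sets for At1g54160, so the planned test of NFYA5 could not be made. The genome build behind the probe annotation was not given in the sources used here, so no coordinates are given, and the gene table served only for names and for which genes neighbour each other.

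For the test, 50 was added to each signal before log2, control probe sets were left out, and the 13961 probe sets with a mean signal of at least 100 over the 4 arrays were kept. Of these, 7496 named 1 gene, 290 several and 6175 none. A linear model with 1 term for the group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend in the variance prior), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so none is reported for single genes. Fold changes are on the log2(signal + 50) scale.

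Before the data were examined, 23 gene lists, the alternatives and the rule for naming genes were fixed. Of each gene, the probe set naming that gene alone with the highest mean signal was used. Lists with at least 4 tested members were tested with camera (preset correlation 0.01, two-sided), beside camera with an estimated correlation and fry, and adjusted over the lists. Because most fixed members had no listed probe set, 22 lists of gene families were drawn up from the annotation after the annotation and signals were seen and before any difference was computed, and 1 list of peroxidases was drawn up by locus, from general knowledge of the family, after the results were seen. The text names the 12 largest rises and 12 largest falls among probe sets that passed, name 1 gene and had groups that did not overlap, up to 4 members of each list that passed or, where none did, up to 2 with the smallest p, and the reference genes. The rule was applied to the added lists as well, and of those lists the text names only some members. Other genes, such as rpl33, rps18, psbE, clpP, COR47, GSTF4, GSTU26, SWEET11, LHCB4.3 and the peroxidases of the closing section, were chosen after their values were seen.

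The test was tried on simulated data with the spread of these arrays, over 13961 probe sets in 10 simulations with 200 changed probe sets each. It called 45.1% of 1.5-fold changes, 92.5% of 2-fold changes and 100% of 4-fold changes, and 4.53% of its calls were false. Camera found a simulated list of 20 genes shifted by 0.5 log2 units in 100% of 50 simulations, and an unshifted list in 6%. These simulations held no correlation between genes, and their spread was drawn from the intensity trend and prior that the test itself had fitted. A share of false calls near the threshold was thus built in, and the simulations do not test whether that prior holds for these arrays. The alternatives were other pseudocounts (1, 16 and 100), no filter or a minimum of 250, quantile normalization, centring on the median, a constant or robust variance prior, the replicate number as a block, each array left out in turn, and only unshared probe sets naming 1 gene. Counts without plastid-encoded probe sets were added after the data were seen. All 4 arrays and no other sample columns were used.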

Results

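Transcript levels were measured with Affymetrix oligonucleotide arrays in whole Arabidopsis thaliana seedlings of the Col-0 accession. The seedlings were 2 weeks old, had grown at 22 °C on agar medium with 3% sucrose under 16 h of light and 8 h of dark, and had received no treatment. Of the 4 arrays, 2 came from wild type and 2 from plants titled as overexpressing At1g54160. This locus encodes NFYA5 (NF-YA5), a subunit of a transcription factor complex that binds the CCAAT box of promoters. The sample titles name an overexpressor, whereas the design text of the series names an nfya5 mutant. The titles were followed, and the second group is called the overexpressor arrays throughout. The level of NFYA5 itself, which would check that label, was not analysed here, because the probe annotation used lists no probe set for At1g54160. Each array gave a signal for 22810 probe sets, with a median signal between 181.4 and 194.1 arbitrary units. Over the tested probe sets the log2 signals correlated at 0.989 between the wild type arrays, at 0.988 between the overexpressor arrays and at 0.979 to 0.985 across the groups. Between 0.237% and 0.289% of probe sets had identical values on any pair of arrays, so no array was a copy of another. With 2 arrays per group, the number of arrays limits the precision of every value.

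The comparison of the groups asked which transcripts differed between wild type and the NFYA5 line in unstressed seedlings, in a study whose title links the gene to drought resistance. Cold- and dehydration-regulated COR15A and COR15B, which encode proteins that protect chloroplast membranes, were a little over 2-fold higher in the overexpressor arrays. GSTU25, GSTU20 and GSTU22, glutathione S-transferases of the detoxifying tau class, were also higher, as were 5 genes in a run of 6 neighbours of the plastid genome, among them petG, which encodes a subunit of the cytochrome b6f complex. Lower in the overexpressor arrays were the dehydrin gene LTI30, the asparaginase gene ASPGB1, the sugar transporter gene SWEET2, and the auxin-conjugating enzyme gene WES1 (also GH3.5), whereas class III peroxidase genes moved in both directions. In all, 180 of 13961 tested probe sets passed an adjusted p of 0.05 in limma's moderated test, 74 of them higher and 106 lower. The median fold was 1.62 among those that were higher and 1.54 among those that were lower, on the signal + 50 scale, which understates the change of dim probe sets. Among the probe sets naming 1 gene, 42 were higher and 48 were lower.

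**Figure D1:**
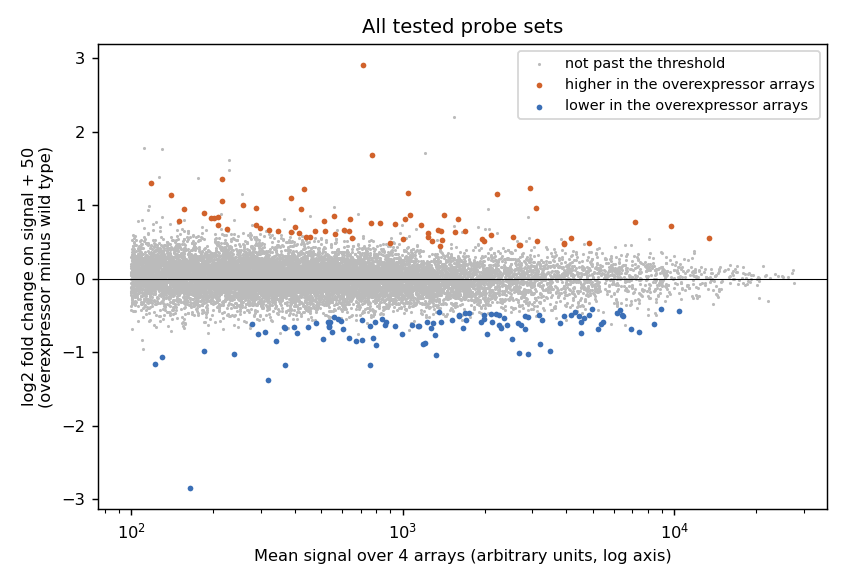
Each point is 1 of the 13961 tested probe sets, with its mean signal over the 4 arrays on a log axis and its log2 fold change, overexpressor minus wild type, on the vertical axis. The 74 probe sets in orange were higher and the 106 in blue lower past the adjusted threshold, and most lie within 2-fold of no change.

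The number of calls depended on the settings. With a constant variance prior in place of one that follows intensity 9 probe sets passed, and with no filter on low signals, where the prior still followed intensity, 1 passed. Without wild type replicate 1 there were 101 calls, without wild type replicate 2 there were 333, and without overexpressor replicate 2 there were 489. All 180 calls had the same direction under every one of these settings, which says little. The variance prior and the filter do not enter the fold change. All calls naming 1 gene, 42 higher and 48 lower, had groups that did not overlap, so leaving out an array could not turn them. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

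The group of drought- and abscisic-acid-responsive genes moved in both directions. Of its 27 members 4 were tested, of which 2 were higher and 1 was lower. Adjusted over the list alone, 2 were higher and 2 lower. COR15A had a signal of 1358 ± 64.6 in wild type and 3091 ± 321 in the overexpressor arrays (SD, n = 2), a log2 fold change of 1.15 ± 0.10 (SE, adjusted p = 0.0012). COR15B rose from 626 ± 49.1 to 1465 ± 30.8 (SD, n = 2), a log2 fold change of 1.17 ± 0.10 (adjusted p = 0.0012). These genes are neighbours on chromosome 2 of the TAIR10.1 assembly and have similar sequences. Neither probe set carries the suffix that marks shared probes, and cross-hybridisation between them was not measured. LTI30 (XERO2), whose product is a dehydrin, fell from 8489 ± 53.5 to 5299 ± 374 (SD, n = 2), with a log2 fold change of -0.68 ± 0.09 (adjusted p = 0.0093). COR47, another dehydrin gene, had a log2 fold change of -0.46 ± 0.11, which did not pass over all probe sets (adjusted p = 0.074). The list as a whole had a median log2 fold change of 0.35, which was 0.22 without overexpressor replicate 2, and did not pass (camera, adjusted p = 0.38, and adjusted p = 0.64 with an estimated correlation). Fry, which asks whether the members move one way on balance, gave an adjusted p of 0.033. STZ (ZAT10), the tested member of 9 DREB and cold regulators, had a log2 fold change of 0.07 ± 0.16.

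All 3 tested members of the 22 glutathione S-transferase genes were higher, over all probe sets and adjusted over the list alone. GSTU25 rose from 99.45 ± 20.9 to 331.2 ± 14.7 (SD, n = 2), with a log2 fold change of 1.36 ± 0.16 (adjusted p = 0.0052). GSTU20 rose from 996 ± 70.5 to 1846 ± 49.1, with a log2 fold change of 0.86 ± 0.10 (adjusted p = 0.0049). GSTU22 rose from 127 ± 5.87 to 265.4 ± 16.3, with a log2 fold change of 0.83 ± 0.15 (adjusted p = 0.028), and without wild type replicate 1 it no longer passed. In a wider list of 10 tested glutathione S-transferases, drawn up from the annotation, these 3 were the members that passed, and the other members lay between -0.29 for GSTF4 and 0.24 for GSTU26. That list did not pass as a whole (camera, adjusted p = 0.20, and adjusted p = 0.94 with an estimated correlation), but passed without wild type replicate 1 (adjusted p = 0.038) and without overexpressor replicate 1 (adjusted p = 0.045). Of the antioxidant enzymes, the glutathione reductase gene GR1 was tested and had a log2 fold change of 0.41 ± 0.10 (adjusted p = 0.071). It passed when adjusted over the list alone, where it was the 1 tested member.

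WES1, SWEET2 and ASPGB1, single genes with roles in auxin, sugar and asparagine metabolism, were among the 12 largest falls. WES1, whose product joins auxin to amino acids, fell from 695 ± 21.4 to 399.9 ± 31.5 (SD, n = 2), with a log2 fold change of -0.73 ± 0.11 (adjusted p = 0.019). It was the 1 of 4 tested auxin-responsive genes to pass, over all probe sets and over the list alone, and HAT2, IAA29 and GH3.3 had log2 fold changes of -0.16, -0.16 and 0.08. The auxin list had an adjusted p of 0.11 by camera, of 0.51 with an estimated correlation and of 0.039 by fry. SWEET2 fell from 1260.05 ± 61.0 to 731 ± 21.1 (log2 fold change -0.75 ± 0.10, adjusted p = 0.0093), whereas SWEET11 had a log2 fold change of 0.30 ± 0.09 that did not pass (adjusted p = 0.12). Adjusted over the list alone, SWEET2 was lower and SWEET11 higher. The list of SWEET transporters did not pass as a whole (camera, adjusted p = 0.96). ASPGB1 showed a log2 fold change of -1.04 ± 0.17 (adjusted p = 0.020), with signals of 1052 and 668.4 on the overexpressor arrays against 1784 ± 125 in wild type (SD, n = 2).

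**Figure D2:**
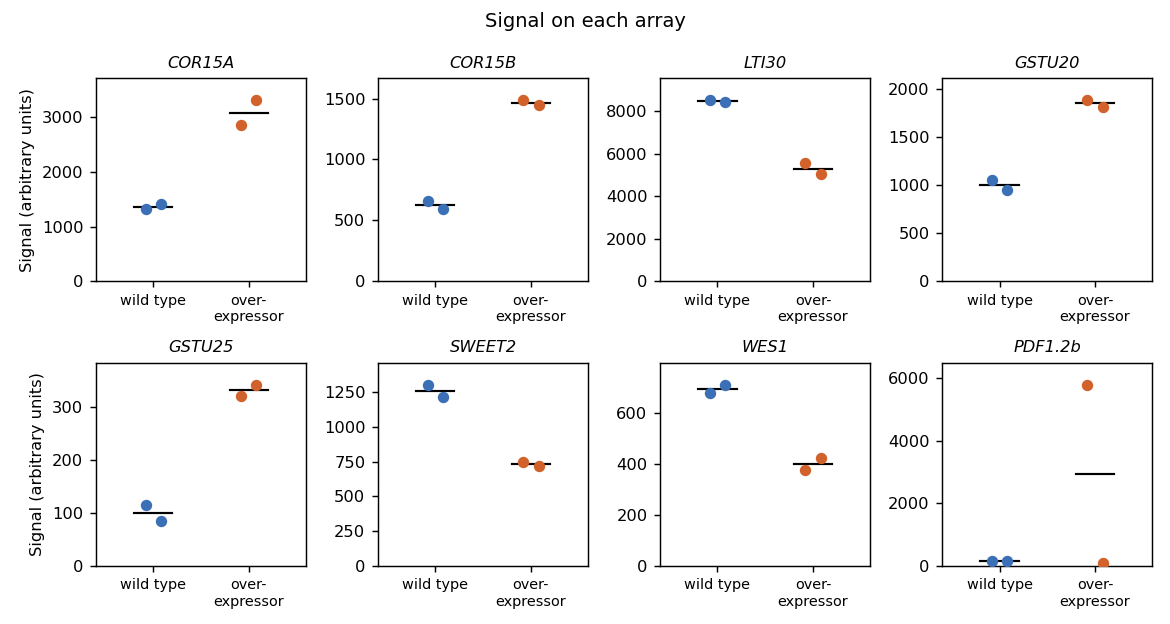
Signal in arbitrary units on each of the 4 arrays for 8 genes, with 1 point per array, a line at the mean of each group and each vertical axis starting at 0. COR15A, COR15B, GSTU20 and GSTU25 were higher on both overexpressor arrays and LTI30, SWEET2 and WES1 lower on both, whereas PDF1.2b was at 5786 on 1 overexpressor array and at 82.5 on the other.

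The remaining rises and falls among the 12 largest in each direction came from several families. AT2G41480, a class III peroxidase gene, rose by a log2 fold change of 1.06 ± 0.16 (adjusted p = 0.017), whereas AT4G26010, another class III peroxidase gene, had a log2 fold change of -0.85 ± 0.11 (adjusted p = 0.0090). AT2G37870, of the lipid transfer protein superfamily, rose from 240.45 ± 2.33 to 629 ± 36.8 (SD, n = 2; log2 fold change 1.22 ± 0.12, adjusted p = 0.0024). AT3G16530, a lectin-like gene, was at 5272 and 3034 on the overexpressor arrays against 2026 ± 113 in wild type (adjusted p = 0.040), and it did not pass without wild type replicate 1 or with a robust variance prior. Its log2 fold change of 0.97 was 0.57 without overexpressor replicate 1. AT5G38900, AT3G16660 and AT5G66470 rose by log2 fold changes of 1.14, 0.95 and 0.85. AT5G38900 was at the threshold (adjusted p = 0.0499754) and did not pass without wild type replicate 2 or without overexpressor replicate 1. AT5G66470 did not pass without wild type replicate 1 or without overexpressor replicate 1, where it had 0.55. The largest fall among named genes was that of AT4G37220, from 531 ± 119 to 205 ± 14.2 (SD, n = 2; log2 fold change -1.18 ± 0.15, adjusted p = 0.0090). AT1G51830, which encodes a receptor-like kinase, had a log2 fold change of -0.98 ± 0.17. AT5G43520 and AT2G44380, which encode cysteine- and histidine-rich domain proteins, had log2 fold changes of -0.87 ± 0.15 and -0.76 ± 0.11. AT4G30670, AT3G57020, AT5G57760 and AT2G37750 had log2 fold changes of -0.84, -0.83, -0.81 and -0.76. Without wild type replicate 1, AT5G43520, AT4G30670, AT3G57020 and AT5G57760 no longer passed, and AT5G57760 also did not pass without overexpressor replicate 1, where it had -0.50, or with a robust variance prior.

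**Figure D3:**
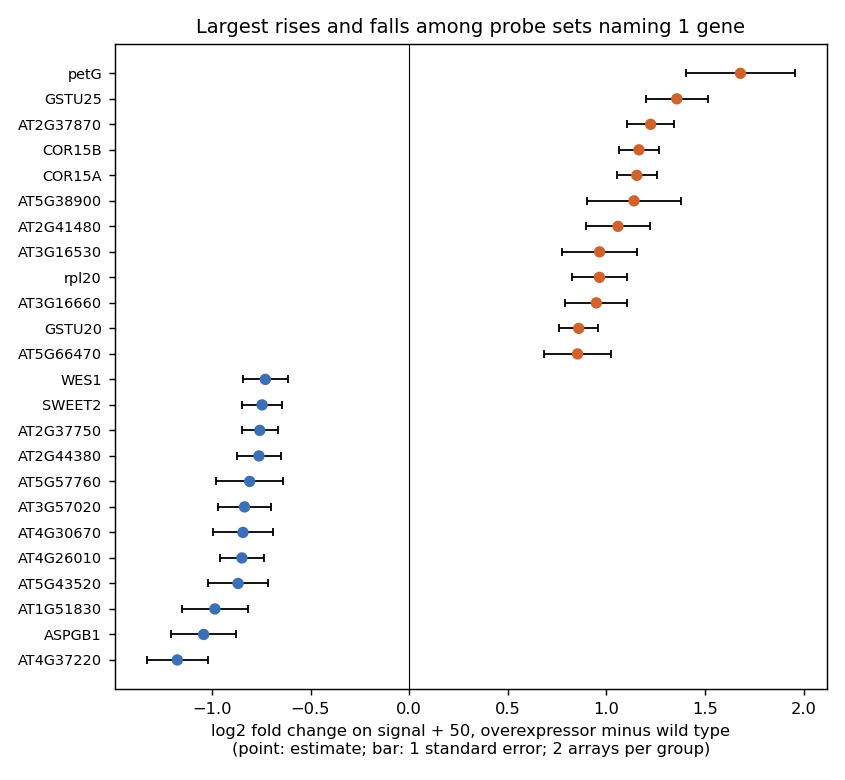
Log2 fold change on the signal + 50 scale, overexpressor minus wild type, of the 12 largest rises and 12 largest falls among probe sets that passed the threshold and name 1 gene, with bars of 1 standard error from limma (2 arrays per group). Rises run from 0.85 for AT5G66470 to 1.68 for petG, and falls from -0.73 for WES1 to -1.18 for AT4G37220.

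Transcripts of the plastid genome had higher signals in the overexpressor arrays as a group. Of 65 tested plastid-encoded genes, 63 had a positive log2 fold change, with a median of 0.35, and 5 were higher past the threshold. Adjusted over the list alone, 21 were higher and 0 lower. The list passed camera (adjusted p = 1.11e-15), and with an estimated correlation, which was 0.67, it did not (adjusted p = 0.94). It also did not pass by fry (adjusted p = 0.48). The list was uneven between the wild type arrays: relative to each gene's mean over the 4 arrays, the mean log2 signal was -0.44 on wild type replicate 1, 0.05 on wild type replicate 2, 0.14 on overexpressor replicate 1 and 0.25 on overexpressor replicate 2. Without wild type replicate 1 the list median was 0.09 (camera, adjusted p = 0.00060), and without wild type replicate 2 it was 0.62. The 5 genes that were higher, petL, petG, psaJ, rpl33 and rpl20, lie within a run of 6 neighbouring protein-coding genes in the TAIR10.1 assembly, the sixth being rps18 (log2 fold change 0.54 ± 0.14, adjusted p = 0.086). petG had signals of 204.9 and 518.4 in wild type and of 1060 and 1290 on the overexpressor arrays, a log2 fold change of 1.68 ± 0.28 (adjusted p = 0.022). It was 1.101 without wild type replicate 1, and petG and psaJ did not pass with a robust variance prior. rpl20, of the plastid ribosome, rose from 179.5 ± 19.5 to 397.7 ± 30.4 (SD, n = 2; log2 fold change 0.96 ± 0.14, adjusted p = 0.012). The tested genes on either side of the run, psbE and clpP, had log2 fold changes of 0.05 ± 0.11 and 0.10 ± 0.10. The run was drawn around the genes that passed, and large values also occurred outside it. There ndhH, rps2 and rps16 had 0.85 ± 0.27, 0.84 ± 0.21 and 0.81 ± 0.24, above petL, psaJ and rpl33, but did not pass. Without wild type replicate 1, psaJ, at a log2 fold change of 0.46, and rpl33 no longer passed. The 20 tested nuclear photosynthesis genes had a median log2 fold change of 0.04 (camera, adjusted p = 0.62), and 0 of them passed in limma's test, where 3 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher, LHCB4.3, with a log2 fold change of 0.47 ± 0.10. The 4 tested mitochondrion-encoded genes had a median of 0.05 (camera, adjusted p = 0.77).

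**Figure D4:**
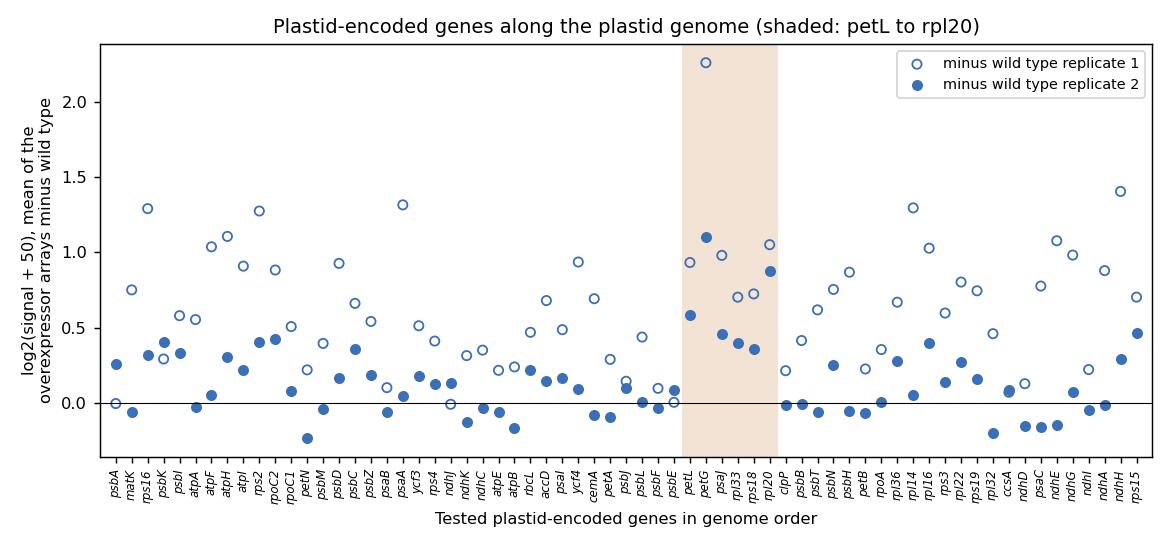
The 65 tested plastid-encoded genes in genome order, with the mean log2(signal + 50) of the overexpressor arrays minus wild type replicate 1 (open circles) and minus wild type replicate 2 (filled circles). The shaded run from petL to rpl20 has a median difference of 0.96 from wild type replicate 1 and 0.52 from wild type replicate 2, where the other 59 genes have medians of 0.56 and 0.08 and some single genes, such as rps2, lie above rpl33 and rps18.

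**Figure D5:**
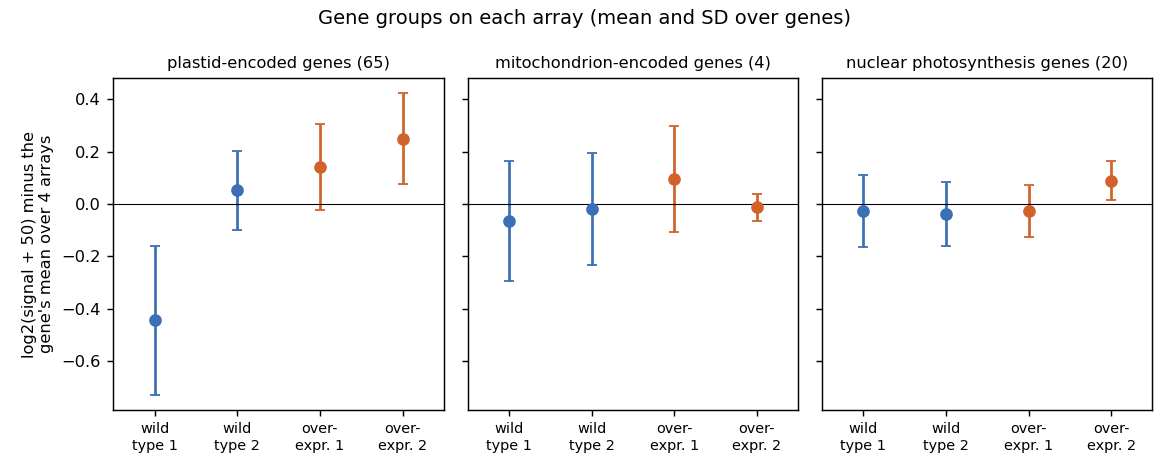
Mean log2(signal + 50) of each gene group on each array, relative to each gene's mean over the 4 arrays, with bars of 1 SD over the genes (65 plastid-encoded, 4 mitochondrion-encoded and 20 nuclear photosynthesis genes). The plastid-encoded genes lie at -0.44 on wild type replicate 1 and between 0.05 and 0.25 on the other arrays.

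The lists meant to show a change in the mix of tissues held few tested members, of which 0 passed in limma's test and 0 had an unadjusted p under 0.05. For green tissue, RCA, LHCB4.2 and LHCB4.1, which serve carbon fixation and light harvesting, had log2 fold changes of -0.06 ± 0.09, -0.04 ± 0.09 and 0.01 ± 0.09. The root markers PYK10 (BGLU23), EXP7 and EXPA18 had log2 fold changes of 0.11 ± 0.09, 0.11 ± 0.15 and -0.37 ± 0.17. For the stomatal lineage, the regulators FAMA and SPCH had 0.10 ± 0.18 and 0.07 ± 0.19. The floral regulator AGL24 had 0.31 ± 0.18 and the clock gene GI -0.02 ± 0.09. Of the reference genes 4 were tested, with log2 fold changes from -0.21 for PEX4 (UBC21) to 0.08 for GAPC2, and 0 passed, at an unadjusted p of 0.05 as well (camera, adjusted p = 0.38). Among early touch and wound response genes, CML38 had a log2 fold change of -0.41 ± 0.12. It did not pass over all probe sets (limma, adjusted p = 0.12) but was lower when adjusted over the list alone. The log2 fold change of CML38 was -0.55 without overexpressor replicate 1 and -0.26 without overexpressor replicate 2. BZIP60, the tested gene of endoplasmic reticulum protein folding, had 0.31 ± 0.11 (adjusted p = 0.18), and passed when adjusted over the list alone, of which it was the 1 tested member.

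Jasmonate-responsive defensin genes differed between the overexpressor arrays more than between the groups. PDF1.2b was at 5786 on overexpressor replicate 1 and at 82.5 on overexpressor replicate 2, against 142 ± 2.55 in wild type (SD, n = 2), and PDF1.2 was at 4434 and 67.1 against 174 ± 31.3. Their adjusted p was 0.39 and 0.51. Without overexpressor replicate 2 both passed as higher, with log2 fold changes of 4.93 and 4.33, whereas without overexpressor replicate 1 PDF1.2b had -0.53 and PDF1.2 passed as lower, with -0.93 (adjusted p = 0.029). The probe set of PDF1.2b carries a suffix that marks probes shared between related sequences.

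Of the 367 gene list memberships fixed in advance, 40 had a listed probe set and 32 were tested, with 5 higher and 2 lower. The NF-Y subunits, abscisic acid synthesis and signalling, salicylate and defence, seed maturation, flavonoid synthesis, phosphate starvation, nitrate, iron deficiency and heat shock lists had 0 tested members and are not analysed here. Of the 3 lists with at least 4 tested members 0 passed camera, where 1 had an unadjusted p under 0.05, and 2 passed by fry. Of 21 tested lists drawn up from the annotation, 1 passed, the plastid-encoded genes, and with an estimated correlation (adjusted p = 0.94) or by fry (adjusted p = 0.48) it did not. Within the others, BGLU44, a beta-glucosidase gene, rose by a log2 fold change of 0.73 ± 0.11 (adjusted p = 0.019), and ATERDJ3B, a chaperone partner gene of the endoplasmic reticulum, by 0.66 ± 0.09 (adjusted p = 0.012). On themes of the untested fixed lists, 10 defence and senescence regulators, 7 iron regulation genes and 7 heat shock co-chaperones were tested. There were also 3 tested flavonoid pathway genes, too few for a list test. In each of these lists 0 members passed over all probe sets. Adjusted over the list alone, 1 defence and senescence regulator was higher and 1 iron regulation gene lower.

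Some of the largest changes were in probe sets with no listed gene, whose identity is therefore not given. The largest fall was in such a probe set, from 326 ± 17.2 in wild type (SD, n = 2) to 2.8 and 1.9 on the overexpressor arrays (log2 fold change -2.84 ± 0.18, adjusted p = 0.00013). The next had a log2 fold change of -1.37 ± 0.14. The largest rise was from 97.9 and 111.6 in wild type to 579.9 and 2072 on the overexpressor arrays (log2 fold change 2.90 ± 0.40, adjusted p = 0.0096), and the next unlisted probe set rose from 47.55 ± 17.0 to 188.9 ± 6.79 (SD, n = 2). Together with GSTU25, AT2G37870, COR15A and COR15B, these made up the 6 probe sets that were at least 2-fold higher and the 2 that were at least 2-fold lower in all 4 pairings of an overexpressor with a wild type array. The other 2 ways of splitting the 4 arrays into pairs gave 0 such probe sets in either direction. Each of these pairs a wild type with an overexpressor array, so a difference between the groups itself works against such counts. With 1 array left out, and so fewer pairings, the counts rose to as many as 33 higher and 12 lower, both without overexpressor replicate 2, and to 16 higher without wild type replicate 2, and the lower counts were 6, 4 and 8 without wild type replicate 1, wild type replicate 2 and overexpressor replicate 1. The groups did not overlap for 48.1% of tested probe sets, where chance gives 33.3%.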

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

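The list of plastid-encoded genes and the other lists drawn up from the annotation, the peroxidase list and the counts without plastid-encoded probe sets were chosen after seeing the data, and the other alternatives before. NFYA5 was not analysed here, so the alternatives meant for it were not run. All 180 calls kept their direction in every alternative that tested them, and of the 32 named genes that passed, 31 still passed with each other pseudocount, 29 with quantile normalization, 32 with centring on the median, 28 with a robust variance prior, 22 without wild type replicate 1, 5 with a constant variance prior and 0 with no filter on low signals. The kept direction says little, since the variance prior, the filter and the replicate block leave the fold change as it is. For calls naming 1 gene, whose groups did not overlap, leaving out an array could not turn it either. The probe sets past the threshold numbered 1 with no filter on low signals (0 higher, 1 lower) and 9 with a constant variance prior (6 higher, 3 lower). With no filter 22746 probe sets were tested. They numbered 56 among unshared probe sets naming 1 gene (24 higher, 32 lower), where fewer were tested. Leaving out each array in turn gave 101 to 489 calls, 44 to 238 of them higher and 57 to 251 lower: 101 without wild type replicate 1, 333 without wild type replicate 2, 230 without overexpressor replicate 1 and 489 without overexpressor replicate 2. In these fits the lone array is assumed to vary like the other group. Without plastid-encoded probe sets there were 214 calls, 85 higher and 129 lower. Quantile normalization gave 160 calls and centring on the median 204.

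The probe sets at least 2-fold higher in all pairs numbered 11 with a pseudocount of 1 and 3 with a pseudocount of 100, and those lower numbered 6 with a pseudocount of 1 or 16, 1 with a mean signal of at least 250 and 0 among unshared probe sets naming 1 gene. With an array left out they ranged from 8 to 33 higher and from 4 to 12 lower, over fewer pairs. By fry 2 fixed lists passed, where camera gave 0. Of the added lists, 0 passed with an estimated correlation, 0 by fry, and 1 to 3 with an array left out. The median of the peroxidase list turned from -0.065 to 0.0104 with no filter on low signals, where more dim members were tested. With an array left out it ran from -0.070 to -0.131. Other list medians near 0 turned too. Without overexpressor replicate 2, for example, that of the nuclear photosynthesis genes went from 0.038 to -0.019. That of the cold, dehydration and osmotic stress genes went from -0.016 to 0.041. The cause of the other changes was not tested.

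With the replicate block, 1075 probe sets passed (525 higher, 550 lower), along with 2 fixed and 2 added lists. The block leaves less information on the spread of each probe set, so these p-values lean more on the variance prior. The rise in calls therefore does not show a shared batch. The labels do not say that a number marks a shared batch, and the deviations of the replicates with number 1 in the 2 groups correlated at 0.056, so the numbers are not known to pair the samples. Of 18 hybridisation control probe sets, 17 were lower on replicate 1 than on replicate 2 in both groups, and the ratio of COR15A to COR15B was too, a hint from the data and not from the design. Several of these control probe sets read the same transcript on the same array, so they are not separate observations. All 180 calls remained with the block. Low signal limits the dim probe sets, since at least 38.2% of the values on each array lay under 100.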

Other observations

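The tests of explanations, the split of the arrays apart from its 2-fold counts, the grouping of plastid genes by their place and the peroxidase list were chosen after the results were seen. The class III peroxidases, secreted enzymes that act on cell walls, moved in both directions. Of 73 family members 55 had a listed probe set and 33 were tested, of which 4 fell and 2 rose. Adjusted over the list alone, 9 were lower and 4 higher. As a set the list was tested by itself, so its camera p-values were not adjusted over the other lists. Beside AT4G26010, the genes AT1G30870, AT3G01190 and AT2G37130 fell, with log2 fold changes of -0.65 ± 0.12, -0.60 ± 0.10 and -0.56 ± 0.11 (SE, limma, adjusted p = 0.034, 0.025 and 0.038). Beside AT2G41480, the gene AT4G36430 rose by 0.57 ± 0.11 (adjusted p = 0.033), and the neighbours AT4G08780 and Prx37 had 0.73 ± 0.16 and 0.56 ± 0.12, which did not pass (adjusted p = 0.0505 and 0.0517). The list passed camera (p = 0.020) but not with an estimated correlation (p = 0.33), nor without wild type replicate 2 (p = 0.14) or overexpressor replicate 1 (p = 0.097). Without wild type replicate 1 there was 1 fall and 1 rise past the threshold, those of AT4G26010 and AT2G41480, without overexpressor replicate 1 there were 2 of each, and without overexpressor replicate 2 there were 8 falls and 3 rises. Further genes that passed, in no list, moved in both directions. The cytochrome c gene CYTC-2 rose by 0.82 ± 0.12 (adjusted p = 0.013), and formate dehydrogenase FDH and isovaleryl-CoA dehydrogenase IVD had -0.50 ± 0.10 and -0.54 ± 0.10 (adjusted p = 0.044 and 0.032). The peptide hormone genes RALFL33 and CLE41 had -0.69 ± 0.13 and 0.65 ± 0.12 (adjusted p = 0.031 and 0.035). Of these, FDH, IVD and RALFL33 did not pass without wild type replicate 1, FDH and CLE41 did not pass without overexpressor replicate 1, and CLE41 did not pass without wild type replicate 2.

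The peroxidases that fell may point to a smaller share of root in the overexpressor seedlings, since many of the family are expressed in roots. The root markers fixed in advance had a median log2 fold change of 0.11 over 3 members, against -0.63 for the 4 peroxidases. EXPA18, at -0.37 ± 0.17, goes with a smaller share, and was at -0.53 without wild type replicate 1 and at -0.20 without wild type replicate 2. PYK10 and EXP7, at 0.11 ± 0.09 and 0.11 ± 0.15, showed no fall, and the abundant PYK10 was at 12749 against 11785. The 4 peroxidases were picked because they fell, from a list drawn up after the results were seen. Set against them, 3 markers that move both ways cannot decide whether the share of root was smaller. After quantile normalization all 4 were still lower and past the threshold. The arrays already had median log2 signals between 8.96 and 8.99 over the tested probe sets, so this step could move the falls little. It therefore tells little about other effects of the scaling. An effect of the NFYA5 line itself stays open.

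The petL to rpl20 run of the plastid genome held all 5 plastid-encoded genes that passed. Against wild type replicate 2 the list median was 0.095, a little below the gap of 0.105 between the overexpressor arrays. These values lie close, and the list still passed camera at its preset correlation without wild type replicate 1. A low plastid signal on wild type replicate 1 alone could thus produce most of the shift of the whole list, but a small remaining shift is not excluded. As the whole cause of the single genes past the threshold it is argued against, because in limma's test over all probe sets without wild type replicate 1, where 101 of 13961 passed, 3 of all 65 tested plastid-encoded genes were higher. These were petL, petG and rpl20, with adjusted p = 0.0467, 0.0023 and 0.029. In that test the lone wild type array is assumed to vary like the other group, and petG did not pass with a robust variance prior over the 4 arrays. For psaJ and rpl33, which did not pass without that array, the explanation stays open. Their log2 fold changes were 0.46 and 0.40 without it, against 0.72 and 0.55 over the 4 arrays. On wild type replicate 1 the mitochondrion-encoded genes were at -0.064 (SE 0.115 over 4 genes) and the nuclear photosynthesis genes at -0.026 (SE 0.031 over 20 genes). The plastid-encoded genes were at -0.44, so neither group was as low as these. The standard errors treat genes as independent and come from 1 array, and the mitochondrion-encoded genes are few. A smaller shortfall of organellar transcripts or of green tissue in wild type replicate 1 is therefore not excluded. An effect of the NFYA5 line stays open, as untested.

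COR15A and COR15B were higher while LTI30 was lower, although all are known as cold- and dehydration-induced. In a list of 13 tested genes of cold, dehydration and osmotic stress these 3 were the members that passed, with 2 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.96), with a median log2 fold change of -0.02 and a mean of 0.07. The other 10 members had a median of -0.042 (SD 0.195 over genes) and a highest value of 0.21, against a mean of 1.16 for COR15A and COR15B. Setting aside the members that passed favours a low remainder, but the median of all 13 was low as well. This argues against a rise of the tested genes as a whole by about that much. Related genes such as RD29A, KIN1 and CBF1 had no listed probe set and are not covered. Cross-hybridisation between COR15A and COR15B cannot be told apart from a rise of both, since their log2 fold changes differed by -0.011 with a standard error of 0.145 and cross-hybridisation was not measured, although neither probe set carries the suffix that marks shared probes. The ratio of their signals lay between 1.93 and 2.37 on the 4 arrays.

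The 4 arrays can be split into pairs in 3 ways, and 1 of the 3, the comparison of overexpressor with wild type, gave 180 calls, where the highest of the others gave 0. With 3 splits a share under 0.05 cannot be reached. The other splits had 272 and 200 probe sets at an unadjusted p under 0.05, against 2307. Each of them pairs a wild type with an overexpressor array, so a difference between the groups adds to their spread. That lowers both their calls and these counts, which therefore do not show what spread between arrays alone would give.

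Between the overexpressor arrays 28 tested probe sets differed by at least 2-fold, 25 of them higher on replicate 1, and the 13 of these that name 1 gene were all higher there. Beside the defensins, the defensin-like LCR67 was at 478.4 against 1.5, CCOAMT at 536 against 140.1, and AT1G26380 at 548.4 against 193.9. The control probe sets of GAPDH were higher on both overexpressor arrays in all 3 parts of the transcript, with 5545 and 5449 against 4077 and 4403 at the 3' end. Control probe sets were left out of the test, and which GAPDH gene these read was not analysed. The reference gene GAPC2 had a log2 fold change of 0.08 ± 0.08 and did not pass. No actin or ubiquitin control probe set was higher on both overexpressor arrays than on both wild type arrays.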
